A study of Phaseolus vulgaris with 4 samples.

How the data were processed

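The series holds RNA-seq libraries of the embryo proper and the suspensor of common bean (Phaseolus vulgaris, cultivar G19833). The suspensor is the stalk that joins the embryo proper to the surrounding seed tissue and feeds it early in development. The labels name 2 biological replicates for each region, which makes 4 libraries. Per the labels' protocols, seeds of 1.6 to 2.0 mm were fixed 6 days after pollination, embedded in paraffin and cut into 6 micron sections, and each region was excised by laser capture microdissection. Total RNA (5 ng) was amplified with the Nugen Ovation RNA-Seq kit and the libraries were then amplified over 10 PCR cycles. The labels mention no molecular identifiers, so reads are not taken as independent molecules. The labels call the replicates biological, but they do not give the number of embryos per library or tie a library to individual seeds or plants. Libraries of both regions can therefore share embryos or plants, and the p-values measure only the spread between these libraries. They are too small if replicates of a region share plants.

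The authors deposited one table per library with a gene ID and a value in RPKM, which is reads per kilobase of gene length, scaled by the reads of the library. Bowtie 0.12.7 and bedtools are named in the submitters' processing notes. The genome build, the annotation, the handling of reads that match several genes, and the use of strand are not given in the sources used here. Values of genes with near-identical copies or overlapping neighbours are therefore uncertain. Each table lists only genes with a value above 0, between 18120 and 18867 per library, and 20961 genes are listed in at least one. A gene that a table does not list was set to 0.

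The RPKM values keep the depth, because the authors' values of a gene are whole multiples of what 1 read is worth for that gene in that library. The modal ratio of low values between libraries gave the relative depths. The total behind a library's RPKM values was then taken as the largest number at which gene lengths came out whole. With these totals, a whole length between 30 and 20000 bp gave whole reads in every library that lists the gene for 100% of the 20961 genes, within 1e-05 reads or the rounding of the file. The smallest such length was used, so recovered reads are lower bounds where all reads of a gene share a factor. The procedure was tested on 5996 simulated genes. The simulated library totals came back without error, and 96.4% of the genes listed in all 4 simulated libraries had the right reads in every library. The recovered totals were 60900034 reads for embryo proper replicate 1 and 73408617 for replicate 2, and 56813099 for suspensor replicate 1 and 55135334 for replicate 2. The recovered reads of the listed genes summed to between 97.5% and 98.2% of these totals. Because recovered reads can be too low, the remainder need not lie outside the listed genes. In a gene of 1 kb, 3 reads, the upper limit that a count of 0 allows, correspond to between 0.0409 and 0.0544 RPKM. These limits cover counting error only.

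The regions were compared with limma 3.58.1 in R 4.3.3, on log2(RPKM + 1) with a mean-variance trend and no scaling beyond that of the authors. Genes with at least 1 RPKM in at least 2 of the 4 libraries were tested, which left 15169. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are suspensor minus embryo proper on the log2(RPKM + 1) scale, which understates the change of low genes. The fit was tested on counts drawn from the real genes' means and replicate spread. Changes were placed only in genes with a mean of at least 5 RPKM. The rates of detection below therefore do not cover lower genes, which were 4111 of the 15169 tested. With 200 of 14640 simulated genes changed, 78.8% of those changed by 4 on the log2 scale were called in the right direction, against 9% of those changed by 2 and 1.5% of those changed by 1, and 8 unchanged genes were called. The right calls at these sizes numbered 52, 6 and 1, so unchanged genes were a larger share of the calls than the threshold of 0.05 aims at. With 1500 of 14636 simulated genes changed by 4 on the log2 scale, 91.8% were called, with 59 unchanged genes called.

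The labels give both regions the replicate numbers 1 and 2 without saying that a number marks shared material, so the fit had no replicate block. The blocked fit, other pseudocounts, filters, scalings and priors, and leaving out each library in turn were alternatives. These choices, the design, the lists and the rule for named genes were set before the data were examined. Limma-voom on the recovered reads, the settings tried for the similarity of libraries and all settings of the share of the most read genes were added afterwards.

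The files do not pair the gene IDs with product names, and 0 of the 20961 IDs matched the 34165 genes of the RefSeq table used here. The 35 gene lists fixed by product name (hormone pathways, transcription factor families, cell division, storage, transport, endosperm and seed coat markers) and the 32 fixed by protein motif could therefore not be tested, and no cell type markers were examined. The rule for named genes had taken genes with a product name, members of each list, and the genes with the highest mean in each region, with at most 2 IDs per direction if no names could be had. That limit applied. Named by ID are the 2 genes per direction with the largest absolute log2 fold change among called genes with a mean of at least 10 RPKM in the higher region, and the gene with the highest mean over all libraries. Other genes with a high mean are given by value without an ID. Chromosome numbers are read from the gene IDs. Genes are given by ID, and no function is assigned to them. Other calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.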

Results

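Transcripts of the embryo proper and the suspensor of globular-stage common bean embryos were measured in 2 replicate libraries per region. The read totals recovered from the RPKM values lay between 55135334 and 73408617 per library. At 1 RPKM or more, 13955 ± 677 genes were detected in embryo proper and 13849.5 ± 786 in suspensor (mean ± SD, n = 2 per region). In all 4 libraries, 10271 genes reached this level.

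Libraries of the same region resembled each other more than libraries of different regions. Across the 15169 tested genes, Pearson's r of log2(RPKM + 1) was 0.82 between the embryo proper replicates and 0.84 between the suspensor replicates. Between regions r ranged from 0.56 to 0.60. The mean difference in r within and between regions was 0.25, and 0.15 with no filter on low values. The first principal component separated the regions and held 66.0% of the variance. The second, with 18.6%, separated replicate 1 from replicate 2 in the same direction in both regions. With 2 libraries per region, components after the first mainly hold differences between replicates, so this does not show that the numbers pair the libraries. Same-numbered libraries deviated together only weakly (correlation across genes 0.07). These correlations run across genes, which are not independent replicates.

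The comparison the design implies asks which genes differ in level between the embryo proper and the suspensor at the globular stage. The regions differed in 1523 genes, 10.0% of those tested. Of these, 681 were higher in suspensor and 842 were higher in embryo proper (limma, adjusted p under 0.05). The differences were large, with a median log2 fold change of 3.45 for the genes higher in suspensor and −3.46 for the genes higher in embryo proper. On the log2(RPKM + 1) scale, at least 4-fold differences held for 652 of the suspensor genes and 759 of the embryo proper genes. At least 32-fold differences on that scale held for 100 and 102. These counts understate ratios of mean RPKM. By that ratio, 111 called genes with a mean of at least 10 RPKM in embryo proper exceeded 142.7-fold. The 4-fold count for embryo proper was 470 with a pseudocount of 5. The 4-fold counts for suspensor and embryo proper were 353 and 393 without embryo proper replicate 1, 391 and 610 without embryo proper replicate 2, and 379 and 346 with limma-voom. The median over all tested genes was 0.00. The median SD between replicates was 0.51 in embryo proper and 0.50 in suspensor on the log2 scale, and the smallest difference called was 1.44. Smaller differences were rarely detectable with 2 libraries per region. With suspensor replicate 1 or 2 left out no gene passed the adjusted threshold in limma, with 3189 and 2947 genes at an unadjusted p under 0.05. The spread then came from the embryo proper libraries alone, with prior degrees of freedom of 2.67 and 2.86 in place of 5.77, and the log2 fold change of Phvul.001G054800, for example, was 6.99 and 7.82 in place of 7.40. Without embryo proper replicate 1 the counts were 353 higher in suspensor and 393 higher in embryo proper, and without replicate 2 they were 391 and 618. With no filter on low values limma called 0 genes in either direction, with 4162 at an unadjusted p under 0.05, and limma-voom on the recovered reads, a setting chosen after the data were seen, called 397 and 430.

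**Figure D1:**
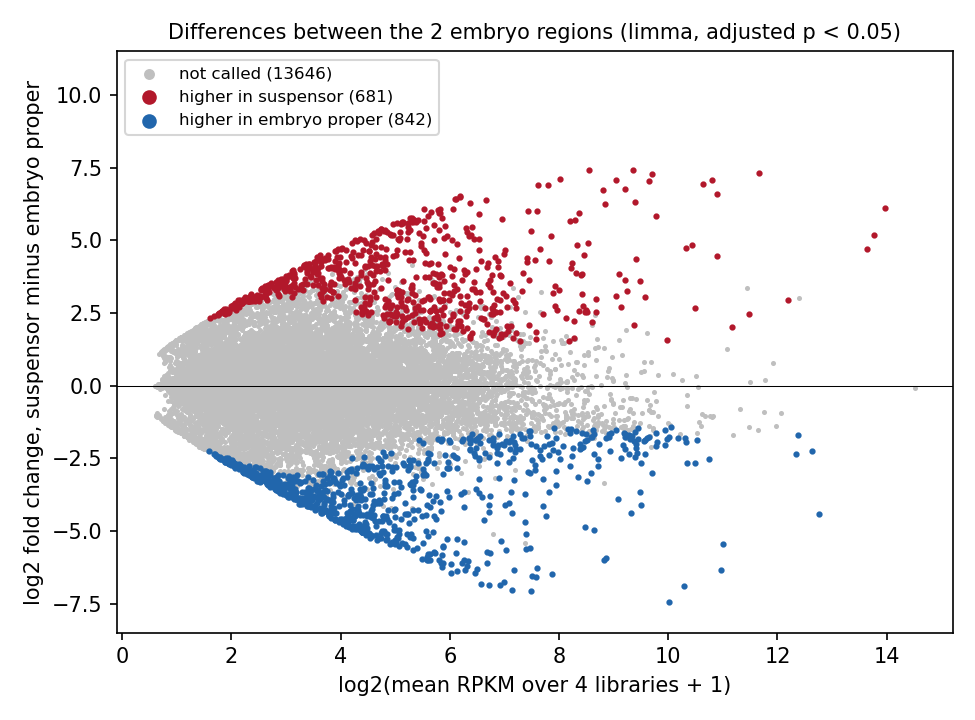
Each point is 1 of the 15169 tested genes. The x axis is log2 of the mean RPKM over the 4 libraries plus 1, and the y axis is the log2 fold change, suspensor minus embryo proper. Red points are the 681 genes called higher in suspensor and blue points the 842 called higher in embryo proper, and no gene with an absolute change under 1.44 was called.

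Called genes were spread over the range of expression, and the share called rose with level. Of the 968 tested genes with a mean of 100 RPKM or more, 31.4% were called, 129 higher in suspensor and 175 higher in embryo proper. Of the 4111 genes below 5 RPKM, 4.06% were called. The log2(RPKM + 1) scale understates the change of low genes, so the rise does not show that abundant genes differed more frequently. The 681 genes higher in suspensor made up 31.7% ± 1.62 of the summed RPKM in suspensor and 2.06% ± 0.259 in embryo proper. The 842 genes higher in embryo proper made up 27.3% ± 0.409 in embryo proper and 4.70% ± 0.645 in suspensor (mean ± SD, n = 2). These genes were chosen on the same libraries, so the shares describe the size of the difference and do not test it.

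Among the 613 genes called higher in suspensor with a mean of at least 10 RPKM there, Phvul.006G197100 on chromosome 6 had the largest log2 fold change on the log2(RPKM + 1) scale, although 38 of them had a larger ratio of means. It averaged 1306 ± 516 RPKM in suspensor and 6.37 ± 0.413 RPKM in embryo proper (n = 2 each), a 205-fold ratio of means. Its log2 fold change was 7.41 with a standard error of 0.45 (limma, adjusted p = 0.000558). Phvul.001G054800 on chromosome 1 followed with 746 ± 295 RPKM in suspensor and 3.24 ± 0.304 RPKM in embryo proper. It was 230-fold higher in suspensor, with a log2 fold change of 7.40 ± 0.49 (SE; limma, adjusted p = 0.000683). Both genes had between 254 and 342 reads in each embryo proper library. These levels were 0.708% and 0.646% of the level in suspensor replicate 2 for Phvul.006G197100 and 0.642% and 0.562% for Phvul.001G054800. Of the 217 genes called higher in suspensor with at least 100 RPKM in suspensor replicate 2, none lay below 0.446% of that level in embryo proper replicate 1 or 0.393% in replicate 2. Both named genes were thus near the lowest share seen in embryo proper, and their ratios do not measure how low the genes were expressed there.

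Among the 738 genes called higher in embryo proper with a mean of at least 10 RPKM there, Phvul.007G099700 on chromosome 7 had the largest log2 fold change on the log2(RPKM + 1) scale, although 111 of them had a larger ratio of means. It averaged 2052 ± 1184 RPKM in embryo proper and 14.4 ± 15.5 RPKM in suspensor (n = 2 each). Its log2 fold change was −7.44 with a standard error of 0.82 (limma, adjusted p = 0.00441). Phvul.003G262100 on chromosome 3 averaged 354 ± 87.7 RPKM in embryo proper, with a log2 fold change of −7.06 ± 0.87 (SE; limma, adjusted p = 0.00590). That change was −5.59 with a pseudocount of 5, −8.82 with 0.1 and −10.81 with limma-voom, so its size depended on the setting. The suspensor libraries differed for both genes. Phvul.007G099700 had 3.42 RPKM in suspensor replicate 1 and 25.3 RPKM in replicate 2, so that its embryo proper mean was 599.8-fold and 81.0-fold higher, respectively. Phvul.003G262100 had 0 reads in suspensor replicate 1 and 428 reads in replicate 2. Its embryo proper mean was 8914-fold the level of 3 reads in replicate 1, a limit that covers counting error only. It was 60.6-fold higher than replicate 2. The levels in suspensor replicate 2 were 0.617% and 0.825% of the sum of both embryo proper libraries, against a lowest value of 0.425% in that library among the 364 genes called higher in embryo proper with a mean of at least 50 RPKM. With replicate 1 left out the log2 fold changes were −6.15 for Phvul.007G099700 and −5.68 for Phvul.003G262100, and with replicate 2 left out they were −8.73 and −8.45. With either suspensor library left out, none of the 4 genes named so far passed the threshold (limma, adjusted p between 0.117 and 0.155).

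**Figure D2:**
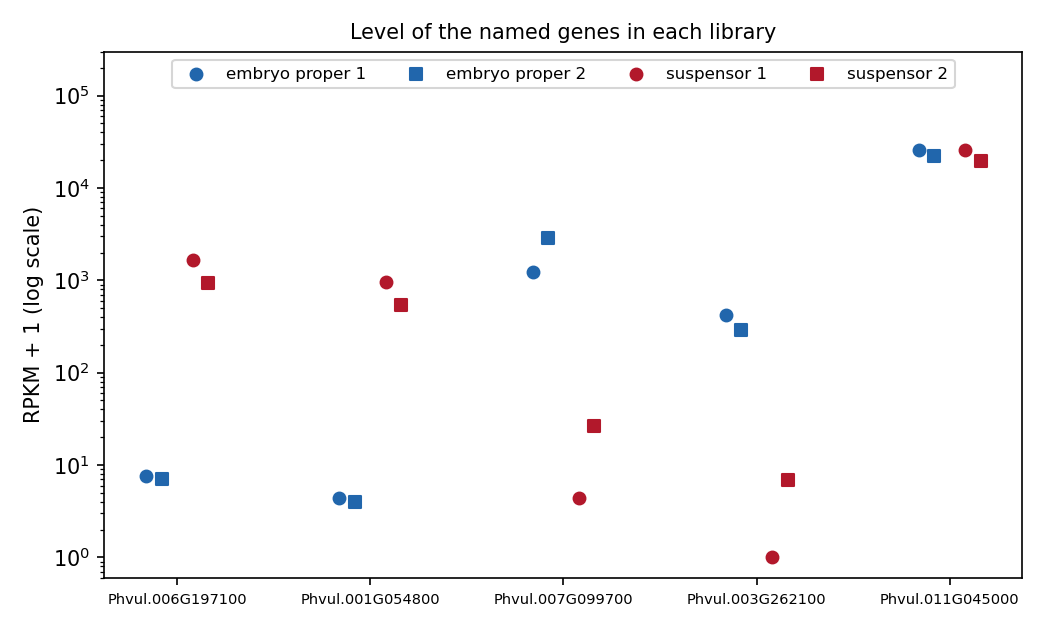
RPKM plus 1, on a log axis, for the 5 named genes in each of the 4 libraries, with circles for replicate 1 and squares for replicate 2. The suspensor points of Phvul.006G197100 and Phvul.001G054800 lie over 2 log10 units above the embryo proper points, Phvul.007G099700 and Phvul.003G262100 show the opposite order with suspensor replicate 1 at 3.42 and 0 RPKM, and the region means of Phvul.011G045000 are 24035 and 22634 RPKM.

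Of the 842 genes called higher in embryo proper, 214 had 0 reads in suspensor replicate 1 and 0 had 0 reads in suspensor replicate 2. The level was higher in suspensor replicate 2 for 565 of the 842 genes and higher in replicate 1 for 277. Of the 681 genes called higher in suspensor, 10 had 0 reads in embryo proper replicate 1 and 6 had 0 reads in replicate 2. Of the 12393 genes with at least 1 RPKM in both embryo proper libraries, 9 had 0 reads in both suspensor libraries. Of the 12259 genes with at least 1 RPKM in both suspensor libraries, 29 had 0 reads in both embryo proper libraries. None of these genes reached 10 RPKM in both libraries of its region. Because abundant genes of one region had reads in 3 of the 4 libraries at a small share of their level, these counts do not measure how many genes were restricted to a region. Under 1 RPKM in both libraries of the other region, the numbers were 894 for embryo proper and 788 for suspensor. The same limit holds for them, because a small share of an abundant gene can reach 1 RPKM.

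The most abundant transcripts differed between the regions. The 10 most read genes took 19.1% ± 1.33 of the reads in listed genes in suspensor and 11.7% ± 1.89 in embryo proper (mean ± SD, n = 2), with each suspensor library above each embryo proper library. With 2 libraries per region the exact two-sided permutation p cannot go below 0.333, which is the value obtained. The most read gene alone took 5.79% ± 0.382 of reads in suspensor and 2.38% ± 0.162 in embryo proper. Both suspensor libraries shared 8 of their 10 most read genes, as did both embryo proper libraries, whereas a suspensor and an embryo proper library shared 3. By mean RPKM, 6 of the 10 highest genes in suspensor were called higher in suspensor, and 4 of the 10 highest in embryo proper were called higher there. The 3 highest genes in suspensor averaged 31799 ± 6059, 27139 ± 16355 and 24713 ± 8793 RPKM and were 67.3-fold, 40.3-fold and 26.5-fold above their embryo proper means, with limma adjusted p of 0.00112, 0.00374 and 0.00374. The second of these was 23.1-fold above the embryo proper mean in suspensor replicate 1 and 57.4-fold in replicate 2. The second highest gene in embryo proper averaged 13299 ± 8946 RPKM and was 24.4-fold above its suspensor mean (limma, adjusted p = 0.00568), or 12.8-fold in replicate 1 and 36.0-fold in replicate 2. The highest gene in embryo proper, Phvul.011G045000, was not called.

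**Figure D3:**
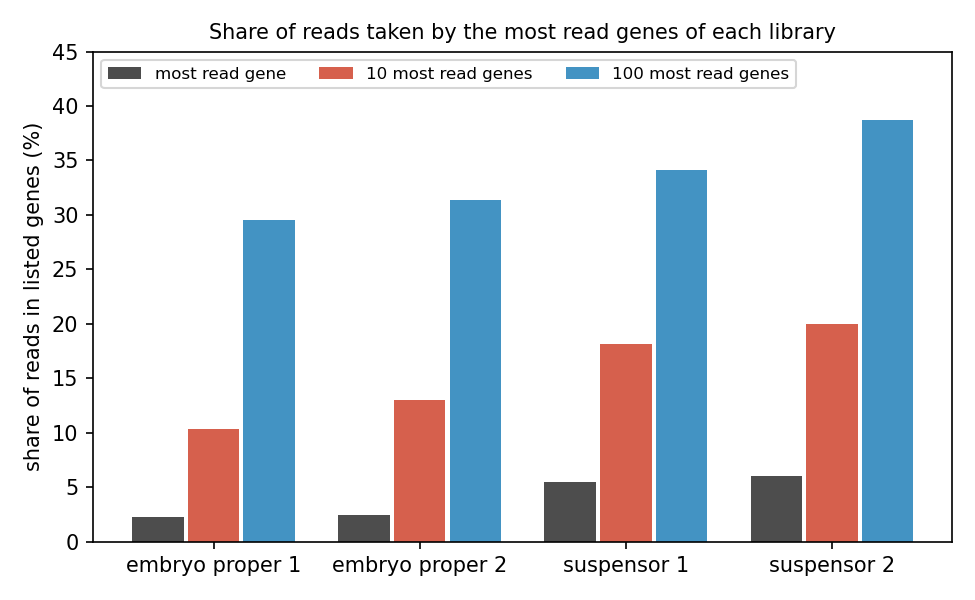
Bars give the share of reads in listed genes, in percent, taken by the most read gene, the 10 most read and the 100 most read genes of each library. The bars for 10 genes reach 10.3% and 13.0% in the embryo proper libraries and 18.1% and 20.02% in the suspensor libraries.

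Phvul.011G045000, on chromosome 11, had the highest mean over all 4 libraries. It averaged 24035 ± 2848 RPKM in embryo proper and 22634 ± 4416 RPKM in suspensor (n = 2 each). Its log2 fold change of −0.10 had a standard error of 0.49 (limma, adjusted p = 0.930), so the difference was within the spread between replicates.

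Genes called in each direction were found on all 11 chromosomes. The share of tested genes called higher in suspensor ranged from 3.13% on chromosome 10 to 6.06% on chromosome 4, and the share called higher in embryo proper from 4.34% on chromosome 6 to 6.56% on chromosome 1. In 22 two-sided Fisher's exact tests of one chromosome against the rest, 0 had an adjusted p under 0.05 and 2 had an unadjusted p under 0.05, with a smallest adjusted p of 0.391.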

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

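Limma-voom and all settings for the similarity of libraries and for the share of the 10 most read genes were chosen after the data were seen. The order of the regions changed for the number of genes detected and, with limma-voom, for the counts at 4-fold or more. Apart from these, no result changed direction under any alternative that was run. Of the 1523 genes called, 0 had the opposite sign under any alternative. At 0.1 RPKM or more, 17124 and 15975 genes were detected in the embryo proper libraries and 17172 and 16143 in the suspensor libraries. The order of the region means was thus opposite to that at 1 RPKM. The counts were 681 genes higher in suspensor and 842 higher in embryo proper, or 652 and 759 at 4-fold or more on the log2(RPKM + 1) scale. Under pseudocounts of 0.1 and 0.5, a mean filter of 5 RPKM, both scalings, no trend, a robust prior and the replicate block, all 4 counts stayed within 1.5 times. With a pseudocount of 5, the embryo proper genes at 4-fold or more fell to 470. With no filter on low values each of the 4 counts was 0 in limma, with 4162 genes at an unadjusted p under 0.05 and prior degrees of freedom of 2.21 in place of 5.77; the cause was not tested further. Limma-voom on the recovered reads called 397 genes higher in suspensor and 430 higher in embryo proper, or 379 and 346 at 4-fold or more, and 757 of the 1523 genes remained called; the cause was not tested. With one library left out, the lone library being assumed to vary like the other region, the counts ranged from 0 to 391 for suspensor and 0 to 618 for embryo proper, and from 0 to 391 and 0 to 610 at 4-fold or more. Leaving out suspensor replicate 1 or 2 gave 0 calls in limma, with 3189 and 2947 genes at an unadjusted p under 0.05. The replicate block called 867 and 1035 genes, and all 1523 genes remained called. Same-numbered libraries deviated together only weakly (correlation across genes 0.07), although the second principal component separated the numbers; with 2 libraries per region neither shows that the numbers pair them. For the 4 genes called and named, 48 of 60 values kept direction and call, and 12 kept direction with an adjusted p of 0.05 or more: those with no filter and those without a suspensor library. The difference between mean within-region and mean between-region r was 0.25, and became 0.30 with a pseudocount of 0.1, 0.22 with 5 and 0.15 with no filter. The excess of the 10 most read genes in suspensor, 7.39 percentage points, ranged from 6.06 to 8.73 with one library left out. The gene list tests were not run, for lack of product names. At 55135334 reads or more per library, 3 reads in a 1 kb gene were at most 0.0544 RPKM, below the 1 RPKM of the filter.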

Other observations

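The tests of the neighbouring genes' placement, of the suspensor libraries and of the region's share of the most read genes were chosen after the results were seen; the test by gene length and the test of over-amplified transcripts were set before theirs. Genes called higher in the same region lay next to each other more frequently than in shuffled calls, although most called genes had no such neighbour. Among 15121 pairs of tested gene models that follow each other in ID order on a chromosome, 61 pairs were both called higher in suspensor, against 30.6 on average when calls were shuffled within chromosomes. In embryo proper 76 pairs were both called higher, against 46.6. The longest run in suspensor held 5 consecutive tested genes on chromosome 11, with log2 fold changes from 3.39 to 4.52 and a longest recovered length 1.13 times the shortest. The longest run in embryo proper held 3 genes.

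Chance placement along the chromosomes is argued against by these counts: over 10000 shuffles the one-sided permutation p for either direction was 0.0001, the smallest they can give. The shuffles did not match genes by level, although 4.06% were called below 5 RPKM and 31.4% at 100 RPKM or more. Whether neighbours of similar level add to the excess was not tested. Near-identical tandem copies of similar length that share reads may account for part of the pattern, since 26.3% of the 137 pairs had lengths within 1.2 times of each other against 19.6% of all neighbouring pairs. The 101 pairs with recovered lengths further apart also exceeded the 62.0 of the shuffles (one-sided permutation p = 0.0001). Copies of similar recovered length thus do not account for all of it. Copies of similar true length cannot be excluded, because a recovered length can be too short. Duplicated genes of unequal length, reads counted for overlapping neighbours without regard to strand, and shared regulation of neighbouring genes stay open. Recovered lengths are lower bounds, and sequences or coordinates of the gene models would be needed to weigh them.

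Some embryo proper transcripts with 0 reads in suspensor replicate 1 had reads in replicate 2, while 628 of the 842 genes called higher in embryo proper had reads in replicate 1 too. Depth is argued against by the totals, since replicate 2 had 0.97 times the reads of replicate 1. A small share of embryo proper RNA or reads in replicate 2 is a candidate explanation. It was examined across the 93 genes with 0 reads in replicate 1 and an embryo proper mean of at least 25 RPKM. Their level in replicate 2 followed the sum of both embryo proper libraries (Spearman's rho 0.8225), at a median of 0.65% of that sum (quartiles 0.57% and 0.75%). Spearman's rho was 0.531 with embryo proper replicate 1 alone and 0.734 with embryo proper replicate 2 alone. The embryo proper libraries showed a like floor for genes high in suspensor replicate 2 and at most 15% as high in the remaining libraries. Of these 58 and 56 genes, 0 lacked reads in embryo proper replicates 1 and 2. None lay below 0.3% of the level in suspensor replicate 2, with lowest values of 0.340% and 0.469%. Reads assigned to the wrong library among these 3 libraries, as within a shared sequencing pool that the labels neither give nor exclude, cannot be told apart from tissue carried over in both directions, which would give such reads too, and a difference between the suspensor samples also stays open.

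Of the 7 genes high in suspensor replicate 1 and at most 15% as high in suspensor replicate 2 and the remaining embryo proper library, 1 lay below 0.3% of that level in embryo proper replicate 1 (0.0581%) and 1 of the 7 so picked in embryo proper replicate 2 (0.121%). Of each 7, 0 lacked reads in the embryo proper library in which they were read. No gene with 0 reads in embryo proper replicate 1, embryo proper replicate 2 or suspensor replicate 2 reached 50 RPKM in another library, whereas 62 genes with 0 reads in suspensor replicate 1 did.

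The 10 most read genes took a larger share in suspensor, and both suspensor libraries shared 8 of their 10. This argues against a different set of transcripts over-amplified in each library. The count does not measure how strongly each library amplified the shared genes, so unequal amplification in single libraries stays open. The lowest suspensor share exceeded the highest embryo proper share by 5.12 percentage points, and with 2 libraries per region a difference between the regions could not reach significance in an exact test, so it stays open. A bias shared by both suspensor libraries was not tested.

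Across the 15169 tested genes, the recovered gene length and the log2 fold change had a Spearman's rho of −0.05.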
